A study of Homo sapiens with 4 samples.

How the data were processed

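RNA was sequenced from C4-2 cells with a control small interfering RNA (2 libraries) or one against EZH2 (2 libraries). Per the labels' protocols, total RNA entered a stranded total RNA library kit. The submitters' processing notes name GRCh38 (hg38), STAR 2.7.10b, featureCounts 2.0.3, edgeR and limma. They give no role or order for these, and the annotation release, the read layout and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene row, not normalised and not pooled, with a row length in bases. It holds 59385 rows, identified by gene symbol or clone name, and every column of counts was matched to its library by the sample titles. Groups and replicate numbers were taken from the titles. Total counts per library ran from 6162123 to 6867542. Between 16480 and 28156 rows had at least 10 counts. Of counts from 1 to 20, between 65.1% and 73.8% were even numbers, so single counts may not be independent reads. Intervals on shares cover counting error only.

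Coordinates are those of GENCODE release 29 on GRCh38. Rows were placed on it by symbol where the symbol occurs once, which placed 37665 rows (63.4% of rows, 57.5% of counts). Of the placed rows 58.1% had the same exonic length as in this release, so the authors' release may differ from it. For each placed row, exons were compared with those of genes on the opposite strand over all annotated isoforms. A minimum overlap of 100 bases was set for pairs of rows and for rows facing exactly 1 coding gene. Shares of rows that overlap a coding gene, and the gene that a named row faces, count any overlap. Rows facing exactly 1 coding gene numbered 3101.

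Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr (24431 kept, 34954 left out), library sizes were scaled by TMM, and groups were compared with glmQLFit and glmQLFTest with no covariate. P-values were adjusted by Benjamini-Hochberg over all kept rows, with calls at 0.05. TMM factors were 0.704 and 0.945 for the siCTRL libraries and 1.12 and 1.34 for the siEZH2 libraries. The common dispersion was 0.216, a biological coefficient of variation of 46.5%. Standard errors were derived from the fold change and its F statistic. The procedure was tested on simulated counts drawn from the libraries' own means and sizes, with 200 rows changed by a known fold. The changed rows were taken from those with a mean of at least 20 counts. Rows were drawn independently, without the trend of fold change with counts described below. The procedure made 1, 2 and 0 false calls at 2-fold, 4-fold and 8-fold. With 2 libraries against 2, an exact two-sided permutation test of a single value cannot give a p below 0.333, so no such test is reported.

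The 30 gene lists, the design, the rule for named genes and the alternatives were set before the data were examined, except where said otherwise. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists. An estimated correlation and fry were run beside it. Each list was also set against 10000 random lists matched on mean expression, a step added after seeing the data. The named genes were EZH2 and each tested PRC2 subunit, the rows with the largest change among those called (there were none), and for each list its called members or, where there was none, the member with the highest mean count. TUBA1B, SORD2P, LTO1, RP11-386G11.10, the rows set beside opposite-strand genes and the olfactory receptor rows were chosen after their values were seen.

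Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, at least 50 counts in 2 libraries, a fold threshold, the replicate number as a block and each library left out. Scaling factors from rows with at least 200 counts in 2 libraries, and a separate fit of 1350 rows facing 1 coding gene, were added after seeing the data. Where leaving out a library leaves 1 in a group, that library is assumed to vary like the other group. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.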

Results

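Gene expression was measured by RNA sequencing in C4-2 cells, an androgen receptor-positive human prostate cancer line derived from LNCaP that grows without androgen. The question was how expression changes when EZH2 is depleted. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 and keeps developmental genes silent. Cells carried either a control small interfering RNA (siCTRL, n = 2 libraries) or one against EZH2 (siEZH2, n = 2 libraries). The deposited counts summed to 6867542 and 6818482 in the libraries labelled siCTRL, and to 6362561 and 6162123 in those labelled siEZH2. The median count per table row was 2 and 4 in the siCTRL libraries and 6 and 8 in the siEZH2 libraries. The labels do not say whether the replicates were separate cultures, so the p-values below measure the spread between these samples, which may be technical.

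The knockdown could not be seen in the table. Counts under EZH2 (GRCh38 chromosome 7, 148807383 to 148884321, minus strand) were 39 and 59 in the libraries labelled siCTRL and 60 and 131 in those labelled siEZH2. Normalised levels were 8.69 ± 0.806 and 12.4 ± 5.39 CPM (counts scaled to library size; SD, n = 2 each). The log2 fold change was 0.51 with a standard error of 0.52 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.621). Leaving out siEZH2 replicate 2 brought it to 0.02, and scaling on well-covered rows alone, a choice made after seeing the data, raised it to 1.23. Because counts under the targeted gene were not lower in the libraries labelled siEZH2, the labels could not be checked from them. That row may also not count the gene's own strand, as described below. Libraries are therefore named below by their labels. Every direction is that of the library labelled siEZH2 against the library labelled siCTRL. Olfactory receptor genes, most of which are silent outside the nose, gave a measure of background. Their 405 rows held 1.30 and 3.14 counts per kb of row length in the siCTRL libraries and 4.64 and 6.27 in the siEZH2 libraries. Counts per kb under EZH2 were 3.62, 5.48, 5.57 and 12.2 in the same order, which is 1.20 to 2.77 times that background.

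**Figure D1:**
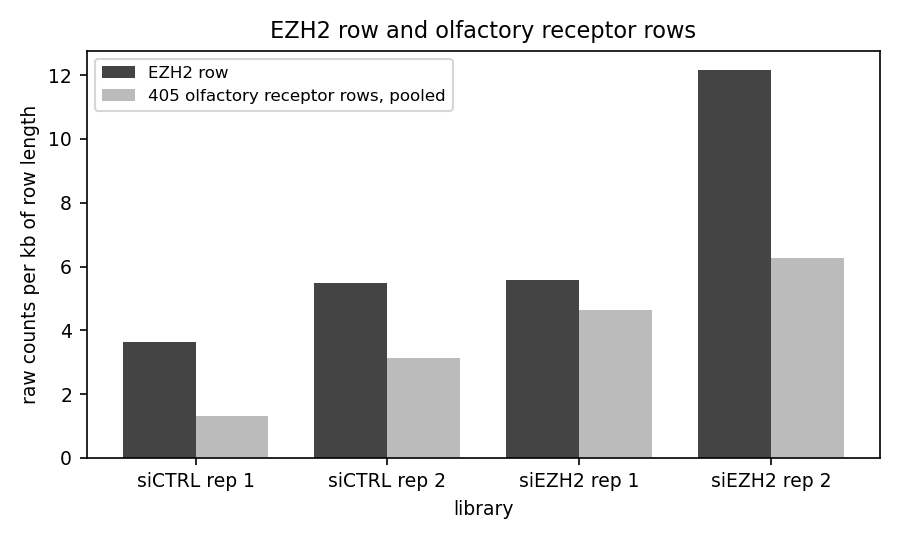
Raw counts per kb of row length in each of the 4 libraries, for EZH2 (dark bars) and for 405 olfactory receptor rows pooled (light bars). Each bar is 1 library, so no error bar is drawn. The EZH2 bar is 12.2 in siEZH2 replicate 2 and 3.62 in siCTRL replicate 1, and the olfactory bars are higher in both libraries labelled siEZH2 than in both labelled siCTRL.

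No PRC2 subunit was called higher or lower. The table holds 13 subunits, of which 10 were tested, and 7 had a positive and 3 a negative log2 fold change. None passed the test over all genes or adjusted over the list alone. EZH1, the paralogous catalytic subunit, stood at 3.52 ± 1.45 and 7.21 ± 0.922 CPM (SD, n = 2 each), a log2 fold change of 1.02. SUZ12 had 0.90, AEBP2 0.99, MTF2 0.76, JARID2 0.53 and PHF19 0.19. The scaffold subunit EED had -0.47, and the histone chaperones RBBP4 and RBBP7, whose rows face SYNC and TXLNG on the other strand, had -0.32 and -0.56. Their edgeR adjusted p ran from 0.443 for EZH1 to 0.918 for PHF19.

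Where the counts lay along the genome bears on what each value measures. The mitochondrial genome carries 13 protein genes, of which MT-ND6 is the only one on the light strand (mitochondrial position 14149 to 14673). MT-ND6 held 53497 and 38229 counts in the siCTRL libraries and 29501 and 41158 in the siEZH2 libraries. MT-CO1, a heavy-strand gene, held 3215, 1552, 1564 and 1789. MT-ND6 alone took between 69.9% and 80.5% of the mitochondrial protein counts. In the nuclear genome, BEST1 (chromosome 11, 61949821 to 61965515, plus strand) held 213179 and 191839 counts against 265907 and 226416. BEST1 encodes a chloride channel of the retinal pigment epithelium. Its exons overlap 1267 bases of FTH1, the ferritin heavy chain gene, on the other strand, and counts under FTH1 itself were 326, 415, 453 and 371. SNX22 opposite PPIB, SH3D19 opposite RPS3A and ATG10 opposite RPS23 held 210, 764 and 682 times the mean counts of the genes they face. Of the 100 protein-coding rows with most counts that could be placed on the annotation, 91 overlap a coding gene on the opposite strand (exact 95% interval 83.6% to 95.8%), against 18.4% of all 18419 such rows with a count. Not every pair went this way. Among 13 pairs of a ribosomal protein or glycolysis gene and a row on the opposite strand, 5 had more counts in the opposite row (38.5%, exact 95% interval 13.9% to 68.4%). DNASE1L1, for instance, had a mean of 343.8 counts against 3897 for RPL10, which it faces. It shares 1102 bases with the main annotated isoforms of RPL10. Some other pairs could hardly show such a difference. PTPN11 and ZWILCH, for example, share 0 bases with the main isoforms of RPL6 and RPL4, which they face. The values below are therefore given as counts under a gene's row, not as levels of its mRNA.

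**Figure D2:**
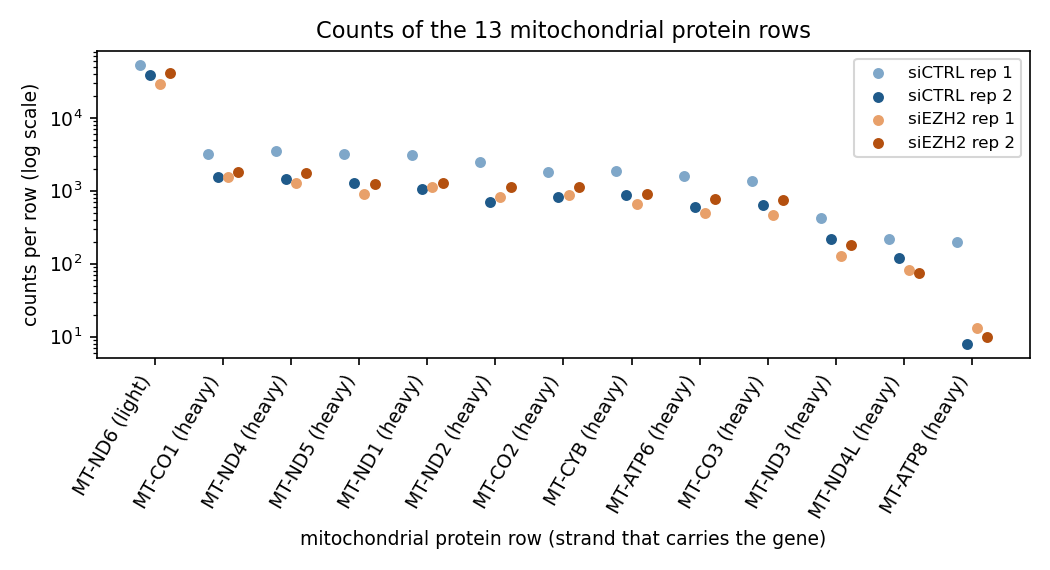
Counts under the 13 mitochondrial protein genes in each library (log scale), with the strand that carries each gene. Each point is 1 library. MT-ND6, the light-strand gene, has 29501 to 53497 counts and lies above MT-CO1, at 1552 to 3215, in each of the 4 libraries.

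Across all genes, no row was called higher or lower. With edgeR, 0 of 24431 tested rows rose and 0 fell at an adjusted p under 0.05, and the lowest adjusted p was 0.159. At an unadjusted p under 0.05 the test gave 2083 rows with a positive and 1932 with a negative fold change. DESeq2 called 10 higher and 858 lower on the same counts, and limma-voom 11 and 334. On simulated counts of the same depth and spread, 200 rows with a mean of at least 20 counts were changed. The test recovered 0% of them at 2-fold, 29.5% at 4-fold and 65% at 8-fold. A change of 2-fold was thus not detectable at this depth and spread. TUBA1B and SORD2P were among the rows that shared the lowest adjusted p, and both were named after their values were seen. TUBA1B, which encodes an alpha-tubulin of the microtubules, had 1023 and 1052 counts against 295 and 265, a log2 fold change of -2.33 with a standard error of 0.42. SORD2P, a sorbitol dehydrogenase pseudogene, had 6 and 6 against 1019 and 18, so that 1 library decided its value.

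The direction of a fold change followed how many counts a row had. Rows with a mean under 20 counts had a median log2 fold change of 0.67 over 7766 rows, and those with 20 to 50 had 0.49 over 8187. The class of 50 to 100 counts had 0.15 over 3912 rows. Above that the median was negative, at -0.52 for 100 to 200 counts, -0.75 for 200 to 1000 and -0.71 for 1000 or more. Positive values made up 23.9% of rows with 100 to 200 counts and 4.46% of rows with 200 to 1000. Of the 959 rows in the last class 1.67% had a positive value. The median over all tested rows was 0.22. Scaling on rows with at least 200 counts in 2 libraries instead of on all tested rows moved it to 0.88, and the rows past an unadjusted p of 0.05 then split into 4400 positive and 272 negative. Of all rows with a mean of 20 to 50 counts 99.7% passed the filter on counts, while in the lowest class the filter can favour rows that are high in 1 group. Pooled over all 405 olfactory receptor rows, with no such filter, normalised levels were 248 and 448 CPM in the siCTRL libraries and 599 and 697 in the siEZH2 libraries. Their log2 ratio was 0.90 (bootstrap over rows, 95% interval 0.77 to 1.02). It was 0.53 without siCTRL replicate 1, 1.38 without siCTRL replicate 2 and 1.53 under the other scaling. The interval does not cover the spread between libraries. Signs below are those under the scaling on all tested rows, and lists whose median changes sign under the other scaling are named. Single genes are not marked in this way. Their small negative values, above and below, may not keep their sign under the other scaling.

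**Figure D3:**
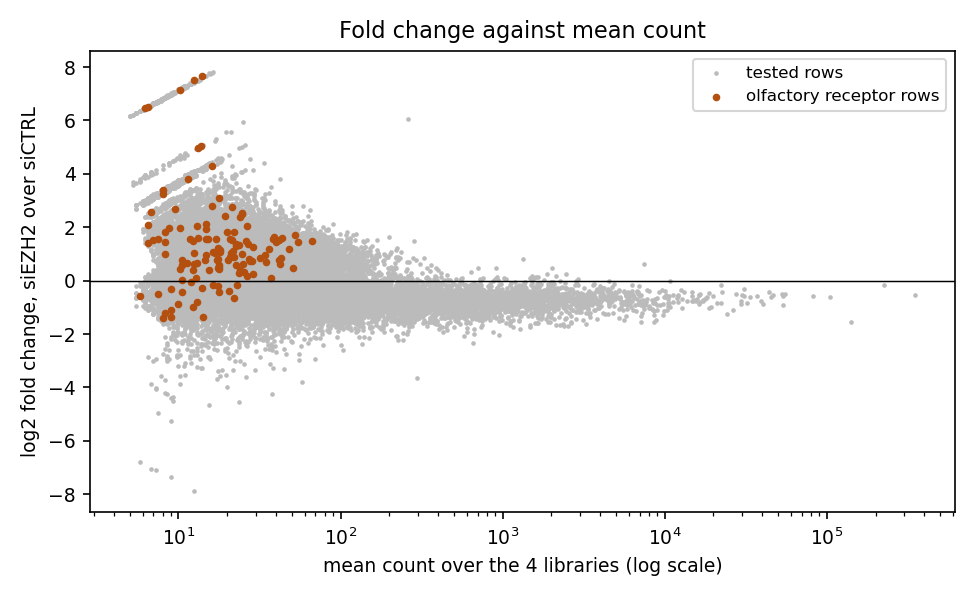
Log2 fold change of each of the 24431 tested rows (siEZH2 over siCTRL) against its mean count over the 4 libraries (log scale). Orange points are the 127 olfactory receptor rows that passed the filter on counts, so their heights depend in part on that filter. Rows with a mean of 1000 counts or more lie mostly below 0, with a median of -0.71, a value that depends on the scaling.

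Counts under the rows of genes under Polycomb control did not stand apart, and those rows may not count the genes' own strand. Developmental transcription factors bound by Polycomb, such as the HOX and PAX families, had 53 of 97 members tested, 32 positive and 21 negative, with a median log2 fold change of 0.38 (camera adjusted p = 0.966). That median lay at the 59.7th percentile of 10000 random lists matched on mean expression. It was 0.10 without siCTRL replicate 1, 0.70 without siCTRL replicate 2 and 0.06 without siEZH2 replicate 2. DLX1, a homeobox gene of forebrain and limb development and the member with most counts, had 90.2 ± 23.5 and 30.9 ± 13.3 CPM (SD, n = 2 each), a log2 fold change of -1.55 with a standard error of 0.43 (edgeR adjusted p = 0.189). Taken over members with a mean of at least 50 counts alone, the list passed in the downward direction (camera adjusted p = 0.0179 with the preset correlation, the estimated one not being run there). These members were set against rows of all counts, and rows with a mean over 100 counts had negative medians. That call therefore cannot be told apart from the trend of fold change with counts. Genes described as EZH2-repressed in cancer had 24 positive and 9 negative members of 33 tested and a median of 0.53 (adjusted p = 0.386), which was 0.23 without siCTRL replicate 1, 0.94 without siCTRL replicate 2 and 0.35 without siEZH2 replicate 2. CIITA, the master regulator of MHC class II genes, had -0.42 there, and its row faces DEXI on the other strand. Before scaling, the CIITA row held 3670 and 4259 counts against 3887 and 4162. PRC1 subunits had 7 positive and 12 negative members with a median of -0.51, which became 0.23 under the other scaling and -0.85 without siEZH2 replicate 1 (adjusted p = 0.0829). PHC1 had -0.77 among them, and its row faces M6PR. The enzymes that remove or oppose methylation of this histone residue had 5 positive and 3 negative members (adjusted p = 0.754), with KMT2C at 0.85. No member of these lists passed over all genes or adjusted over the list alone.

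Of the 30 lists, 11 passed the camera test with a preset correlation, 10 downward and 1 upward, and 0 passed with an estimated correlation or with fry. When rows needed at least 50 counts in 2 libraries, the ribosomal protein, glycolysis and mitochondrial lists still passed. The androgen receptor, epithelial, G1/S, G2/M, fatty acid synthesis and stress response lists then had adjusted p from 0.087 to 0.487, and the basal and antigen presentation lists had under 5 members left and were not tested. Androgen receptor targets fell as a list, with 25 of 34 tested members negative and a median of -0.58 (camera adjusted p = 0.00158, and adjusted p = 0.391 with an estimated correlation). Random lists of like expression had a median of -0.38, and the list did not stand apart from them (resampling adjusted p = 0.273). None passed over all genes and 4 fell when adjusted over the list alone. CENPN, a centromere protein gene in that list whose row faces CMC2, had 423 ± 82.7 and 246 ± 49.7 CPM (SD, n = 2 each). Epithelial genes fell with 14 of 16 negative and a median of -0.64 (adjusted p = 0.00295, and adjusted p = 0.391 with an estimated correlation), and 1 fell adjusted over the list alone. KRT8, a luminal keratin, had 3482 ± 755 and 2084 ± 1190 CPM (SD, n = 2 each), under a row that faces KRT18. The epithelial median was -0.28 without siEZH2 replicate 2. Both list medians turned positive under the other scaling, at 0.12 and 0.01. Basal prostate and androgen receptor-negative line markers were the list that rose, with 9 of 11 positive and a median of 1.33 (adjusted p = 0.0488, and adjusted p = 0.479 with an estimated correlation). Its members had a median of 25.5 counts. The list no longer passed under the other scaling (adjusted p = 0.118), with limma-voom (0.0844) or with no low-count filter (0.379). Nor did it pass without siCTRL replicate 1, where the adjusted p was 0.128, siCTRL replicate 2, where it was 0.0541, or siEZH2 replicate 1, where it was 0.257. CD44, a cell-surface hyaluronan receptor, had 8 and 45 counts against 58 and 61. Neuroendocrine and neuronal genes had 14 of 17 positive (adjusted p = 0.753), 1 of them higher when adjusted over the list alone, with SCN3A at 0.62. Mesenchymal and matrix genes had 17 of 22 positive (adjusted p = 0.386), with FN1, fibronectin, at -0.07.

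The G1/S and G2/M lists passed in the downward direction under the preset correlation. G1/S and DNA replication genes had 27 of 39 members negative and a median of -0.40 (camera adjusted p = 0.015, and adjusted p = 0.391 with an estimated correlation), and the call was lost without siCTRL replicate 1 or siEZH2 replicate 1, at adjusted p = 0.0606 and 0.15, and under the other scaling, at 0.0874. G2/M and mitosis genes had 24 of 38 negative and a median of -0.37 (adjusted p = 0.0029, and adjusted p = 0.391 with an estimated correlation), and the call was lost with at least 50 counts in 2 libraries, at adjusted p = 0.487. Of these 0 passed over all genes and 2 fell adjusted over the list alone. Under the other scaling the medians were 0.36 and 0.29. CCNA2, cyclin A2, whose row faces EXOSC9, had 113 ± 39.2 and 53.2 ± 3.74 CPM (SD, n = 2 each), a log2 fold change of -1.09 with a standard error of 0.41 (edgeR adjusted p = 0.229). MCM2, a subunit of the replicative helicase, had -0.49 under a row that overlaps 45 bases of TPRA1 on the other strand. Homologous recombination genes had 14 positive and 13 negative members of 27 (adjusted p = 0.966), with EME1 at -0.80 under a row that faces LRRC59. Targets of p53 had 16 positive and 10 negative members of 26 (adjusted p = 0.966), with DDB2 at -0.53, and their test pointed down although their median was 0.21. That median was -0.01 without siEZH2 replicate 2, 0.56 without siEZH2 replicate 1 and 0.44 without siCTRL replicate 2.

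The most negative list medians were those of the glycolysis, fatty acid synthesis, ribosomal protein and mitochondrially encoded lists. Glycolysis genes fell with 16 of 20 negative and a median of -0.94 (camera adjusted p = 0.000356, and adjusted p = 0.391 with an estimated correlation), 7 of them when adjusted over the list alone and 0 over all genes. GAPDH had 1514 and 1429 counts against 1051 and 1130, or 269.7 ± 64.3 and 145 ± 7.37 CPM (SD, n = 2 each). Fatty acid synthesis genes had 10 of 12 negative and a median of -0.92 (adjusted p = 0.00158, and adjusted p = 0.391 with an estimated correlation), with 3 lower adjusted over the list alone. FADS1, a fatty acid desaturase gene whose row faces FADS2, had -0.91. Cytosolic ribosomal protein genes had 34 of 35 negative and a median of -0.88 (adjusted p = 2.06e-07, and adjusted p = 0.479 with an estimated correlation), with RPL10, which faces DNASE1L1, at -0.75. Their median was -0.57 without siCTRL replicate 1. Members of this list had a median of 212.5 counts, and 4.46% of all tested rows with 200 to 1000 counts were positive. The share of negative members alone therefore does not set the list apart. Mitochondrially encoded protein genes had 13 of 13 negative and a median of -1.34 (adjusted p = 0.000342, and adjusted p = 0.594 with an estimated correlation), 11 of them lower adjusted over the list alone. siCTRL replicate 1 decided this value. Without it the median was -0.17, with 10 of 13 members negative, and the call was lost at adjusted p = 0.281. MT-ND1, for instance, had 3085 counts in that library and 1057 in the other siCTRL library, against 1130 and 1279. Set against 10000 random lists of like expression, these 4 lists and the G2/M list had medians outside the range of most draws. The draws had medians of -0.46 for glycolysis, -0.44 for fatty acid, -0.63 for ribosomal, -0.71 for mitochondrial and 0.24 for G2/M. Resampling adjusted p was 0.026, 0.0468, 0.0468, 0.006 and 0.024 in the same order. Part of each negative median of the 4 lists was thus shared with rows of like counts. Each draw took its rows independently, so these p-values ignore how members of a list vary together between libraries. The other 6 lists past camera did not pass this comparison, with adjusted p of 0.273 for androgen receptor targets, 0.178 for epithelial, 0.112 for G1/S, stress response and basal, and 0.105 for antigen presentation genes. The medians of the 4 lists stayed negative under the other scaling, at -0.24, -0.24, -0.15 and -0.49. Cholesterol synthesis genes had 13 of 21 negative (adjusted p = 0.0585), with ACAT2, whose row faces SOD2, at -0.87. Ketone body metabolism genes had 6 positive and 6 negative members of 12 (adjusted p = 0.854), with the monocarboxylate transporter gene SLC16A3, whose row faces CSNK1D, at -0.24. Histone deacetylases had 5 positive and 10 negative members of 15 (adjusted p = 0.386), with SIRT3, whose row faces PSMD13, at -0.47. The medians of these last lists changed sign under the other scaling, from -0.38 to 0.40 for cholesterol synthesis, from -0.08 to 0.62 for ketone body metabolism and from -0.37 to 0.26 for histone deacetylases. The cholesterol median was -0.25 without siCTRL replicate 1 and -0.12 without siEZH2 replicate 2, and that of histone deacetylases -0.23 without siCTRL replicate 2 and -0.06 without siEZH2 replicate 2. The ketone body median was -0.54 without siEZH2 replicate 1 and between 0.01 and 0.08 without any other library.

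Stress, immune and other-cell lists showed little beyond this. Genes of the unfolded protein and integrated stress responses had 11 of 20 negative and a median of -0.57 that became 0.11 under the other scaling (camera adjusted p = 0.0342, and adjusted p = 0.471 with an estimated correlation). Of these 2 were lower adjusted over the list alone, and leaving out any 1 library lost the call, with adjusted p from 0.0554 to 0.0702 and a median of -0.34 without siCTRL replicate 1. With no low-count filter the adjusted p was 0.0504. HSPA5, the endoplasmic reticulum chaperone BiP, had 127 ± 7.63 and 47.2 ± 13.6 CPM (SD, n = 2 each), a log2 fold change of -1.43 with a standard error of 0.41 (edgeR adjusted p = 0.191). Antigen presentation genes fell with 10 of 11 negative and a median of -0.76 that became 0.01 under the other scaling (adjusted p = 0.0342, and adjusted p = 0.479 with an estimated correlation), and lost the call without siCTRL replicate 2, at 0.161, or siEZH2 replicate 1, at 0.254, and with limma-voom, at 0.123. Its median was -0.46 and -0.45 without those libraries. ERAP1, whose row faces CAST, had -0.49 there. Interferon-stimulated genes had 25 of 38 positive (adjusted p = 0.386), and MX1 stood at 595 ± 133 and 550.5 ± 167 CPM (SD, n = 2 each). Before scaling, the MX1 row held 3309 and 3193 counts against 4679 and 3497. Chemokine and cytokine genes had 7 of 10 positive (adjusted p = 0.106), with CXCL16, whose row overlaps 85 bases of MED11, at -0.46. Apoptosis regulators had 11 positive and 12 negative members (adjusted p = 0.809), with BCL2L2, whose row faces PPP1R3E, at -1.17. RNA interference genes had 7 positive and 5 negative (adjusted p = 0.912), with TARBP2 at -1.13. Replication-dependent histone genes had 1 positive and 4 negative (adjusted p = 0.338), with H4C5 at -0.60. The apoptosis and histone lists also changed sign under the other scaling, from -0.08 to 0.74 and from -0.60 to 0.12. Leaving out any 1 library made the apoptosis median positive, at 0.04 to 0.34, and the histone median was -0.15 without siCTRL replicate 1 and -0.20 without siEZH2 replicate 1. Among markers of cells that a C4-2 culture should lack, leukocyte genes had 10 of 13 positive (adjusted p = 0.989), with CD68 at -0.64. Fibroblast and endothelial genes had 13 of 15 positive (adjusted p = 0.23), with CLDN5 at -1.43.

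Rows that face exactly 1 coding gene were also tested on their own, a comparison chosen after seeing the data. There were 1350 with at least 100 counts in 2 libraries, and their scaling was set among themselves. With edgeR 1 row rose and 0 fell at an adjusted p under 0.05, and 93 and 74 had an unadjusted p under 0.05. The row that rose was LTO1 (chromosome 11, 69653076 to 69675416, minus strand), whose exons overlap 497 bases of CCND1, the cyclin D1 gene. It held 5362 and 4254 counts in the siCTRL libraries and 11346 and 8860 in the siEZH2 libraries, a log2 fold change of 1.32 with a standard error of 0.18 (edgeR adjusted p = 0.0349). In the fit of all rows its value was 0.61 (adjusted p = 0.503), and the call was lost without either siCTRL library. Rows that face genes of the G1/S, G2/M and homologous recombination lists numbered 10, and 10 of 10 were lower in both siEZH2 libraries than in both siCTRL libraries. Among the other rows 19.4% were, and chance gives 16.7%. LRRC41, which overlaps 806 bases of the recombination gene RAD54L, held 1699 and 1599 against 684 and 684 counts (log2 fold change -1.02, standard error 0.20). POLG opposite FANCI had -0.86, FANCD2OS opposite FANCD2 -0.99, INTS8 opposite CCNE2 -0.80 and ENOSF1 opposite TYMS, the thymidylate synthase gene, -0.72. None of the 10 passed singly. Their median was -0.72, and 10000 random sets of like counts spanned -0.20 to 0.20 over their central 95%. The camera p for the set was 3.52e-08 with the preset correlation and 0.13 with an estimated one.

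**Figure D4:**
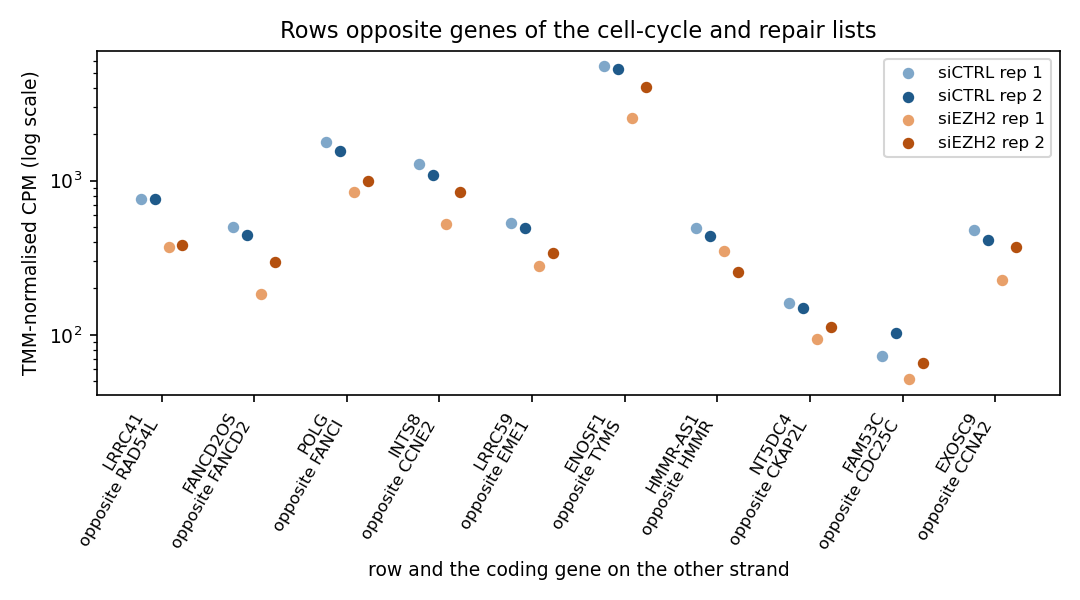
Normalised CPM (log scale) of the 10 rows that face a gene of the cell-cycle and repair lists, by library. Each point is 1 library. In 10 of 10 rows both siEZH2 points lie below both siCTRL points, with a median log2 fold change of -0.72 under scaling set among rows that face 1 coding gene.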

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

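The scaling on rows with at least 200 counts, the matched random lists and the separate fit of rows that face 1 coding gene were chosen after seeing the data, and the other alternatives were set beforehand. The counts of rows called higher and lower were 0 and 0, and stayed so with upper-quartile factors, the 50-count filter and scaling on well-covered rows. A fold threshold on the main fit could only leave them at 0 and 0. RLE factors gave 1 and 12, no low-count filter 12 and 68, limma-voom 11 and 334, and DESeq2 10 and 858, with 19420 adjusted p-values not given by DESeq2. Leaving out 1 library gave 0 to 78 higher and 0 to 143 lower: siEZH2 replicate 1 gave 78 and 143, siEZH2 replicate 2 gave 10 and 48, and either siCTRL library gave 0 and 0. The cause of these differences was not tested. The labels do not say that replicate numbers pair the libraries. A replicate block gave 248 higher and 1079 lower. The differences of replicate 1 from replicate 2 had a correlation of 0.0696 between the groups, taken over the 24431 tested rows. EZH2 ran from 0.02 to 1.23 over 12 alternatives, with adjusted p from 0.282 to 0.996. The 11 lists past camera became 3 with the 50-count filter (ribosomal protein, glycolysis and mitochondrial), 0 with an estimated correlation, 0 with fry, and 7 to 10 without 1 library, the lowest being without siCTRL replicate 1 or siEZH2 replicate 1. Members with a mean of at least 50 counts, set against rows of all counts, gave 12 lists. PRC1 subunits and cholesterol synthesis (camera adjusted p = 0.0104 each) were among them. That setting does not separate a list from the trend of fold change with counts. The number with limma-voom was 10, with PRC1 subunits at 0.0394. Scaling on well-covered rows gave 9, without the G1/S and basal lists, and no low-count filter 9, without the stress response and basal lists. Values of the 38 other named genes, 452 in number, were counted over all settings together. Of these 402 kept their sign and their side of the threshold, and 24 became called in the same direction. Another 26 uncalled values changed sign, and 0 called values reversed. For LTO1 among rows that face 1 coding gene, the call was lost with RLE factors, with the factors of all rows and without either siCTRL library. Those factors gave 0 higher and 103 lower, and leaving out siEZH2 replicate 1 or 2 gave 78 higher with 101 or 119 lower. The median of the 10 rows that face cell-cycle and repair genes ran from -0.55 to -1.40. Simulated 2-fold changes were not recovered at this depth, spread and number of libraries, and depth alone was not varied.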

Other observations

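Tests on the ranks of ribosomal protein rows, on the mitochondrial rows, on the olfactory receptor rows and on the rows that face cell-cycle genes, background subtraction included, were chosen after the result was seen. The other tests were set before their result was seen.

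Some rows outside the comparisons above are given as values. Among rows that face 1 coding gene, fitted on their own, KIF7 opposite TICRR, a replication initiation gene, had a log2 fold change of -1.22, TRIM59 opposite the condensin gene SMC4 -0.80 and TMPO-AS1 opposite TMPO -0.72. SYNC opposite RBBP4, which encodes a PRC2 subunit, held 11944 and 9809 counts against 7133 and 6830, a log2 fold change of -0.38 with a standard error of 0.15. BEST1 opposite FTH1 and MRNIP opposite SQSTM1, the autophagy receptor p62, each had 0.53. None of these passed the edgeR test. A clone-named row that was not placed on the annotation, RP11-386G11.10, chosen after its values were seen, held 194025 and 190285 counts against 92279 and 87379, a log2 fold change of -1.55 in the fit of all rows (edgeR adjusted p = 0.247).

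Rows of abundant genes hold few counts while rows on the strand opposite them hold many. Antisense transcripts counted beside correctly counted sense transcripts were argued against: 9 of 35 ribosomal protein rows (25.7%, exact 95% interval 12.5% to 43.3%) were among the 1000 coding rows with most counts, where correct counting would put most of them, although reads shared with pseudogenes were not measured. A candidate explanation is that reads were counted on the strand opposite the transcript, as can happen with a stranded kit and the other strand setting, and the MT-ND6 share of at least 69.9% of mitochondrial protein counts goes with it. The test set beforehand did not come out that way, since 38.5% of ribosomal and glycolysis pairs had more counts in the opposite row. Its interval of 13.9% to 68.4%, a criterion added after that result was seen, leaves it undecided. Pairs such as PTPN11 and RPL6, sharing 0 bases with the main isoform of the gene faced, could not have shown it. If reads were counted on the opposite strand, the EZH2 row does not count EZH2 transcripts and says nothing of the knockdown. No coding gene faces EZH2 in the annotation used, so no such row could be read in its place.

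Low-count rows mostly have positive fold changes in the libraries labelled siEZH2, with a median of 0.49 for tested rows of 20 to 50 counts. Derepression of Polycomb targets would be the biological reading, and higher background in those libraries, for instance from genomic DNA or intronic RNA, is a technical one. All 405 olfactory receptor rows pooled, with no filter on counts, had a log2 ratio of 0.90 (0.53 without siCTRL replicate 1, 1.38 without siCTRL replicate 2), so background may account for part of these values. The Polycomb-bound list did not pass its test, with 32 positive and 21 negative members, and stood at the 59.7th percentile of matched lists, a comparison added after other results had been seen but with its bound set before that percentile was computed. Whether its transcripts changed cannot be told apart from no change here, because the MT-ND6 share leaves open that those rows do not count the genes' own strand.

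Rows that face cell-cycle and repair genes are lower in the libraries labelled siEZH2. Subtracting the olfactory background per base from all rows that face 1 coding gene left the median relative to rows of like counts at -0.80, against -0.76 before, but it moved rows of like counts by only 0.03 and so does not decide whether unequal background plays a part. A hypothesis is that these rows count the transcripts of the genes they face, and that cell-cycle transcripts may be lower in the libraries labelled siEZH2. The set's p was 3.52e-08 with a preset correlation and 0.13 with an estimated one, so lower cell-cycle expression cannot be told apart from 10 rows that vary together between 4 libraries. The higher counts of LTO1, which faces CCND1, go the other way for a cell-cycle gene. On this hypothesis, counts under the own rows of cell-cycle genes, such as CCNA2 and EME1, would not measure those genes. The 2 kinds of row differ for homologous recombination genes. Their own rows had 14 positive and 13 negative members, while 4 of 4 rows facing them were lower, with a median of -0.92.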
